A study of Mus musculus with 5 samples.

How the data were processed

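Single cells from placentas of CD1 mice at E7.5, E8.5, E10.5, E11.5 and E12.5 were sequenced with 10x Genomics Chromium 3' v3 chemistry, 1 library per day. Placentas were pooled before dissociation, per the labels' protocols, so no cell can be traced to an animal. The deposited matrices hold UMI counts per gene and barcode, which the authors made with Cell Ranger 3.0.2 on mm10, per the file headers and the submitters' processing notes. Seurat is named there without a version or a role. The aligner settings and annotation release are not given in the sources used here. Every deposited barcode had at least 500 UMIs, so shallower droplets were not available.

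Of 31053 gene IDs, 31011 were matched to GENCODE M21, which gave positions on mm10 (GRCm38). Cells with fewer than 500 genes or more than 15% mitochondrial UMIs were removed. Among cells of at least 200 genes and at most 25% mitochondrial UMIs, doublets were scored per library with Scrublet in scanpy 1.11.5. Scrublet's own threshold was used for E11.5 and E12.5. It marked under 0.5% of the other libraries, where the highest scores were removed instead, 0.8% per 1000 cells. Doublets were 10.2, 8.57, 7.47, 3.65 and 2.21% of scored cells in the order of days. The genes filter removed 2328, 1501, 3246, 2307 and 2282 cells and the mitochondrial filter 543, 947, 74, 150 and 95.

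Kept cells of all libraries were clustered together without a correction between libraries, because library and day are the same. Counts were scaled to 10000 UMIs per cell and log-transformed. The 2000 most variable genes within libraries gave 30 principal components, 20 neighbours, a shared-neighbour graph and Leiden clusters at resolution 1 with seed 0 (igraph 0.11.9, scikit-learn 1.9.0). Clusters were named from 26 marker lists, 8 of them for trophoblast, by the mean log2 level of a list's genes over the other clusters. A name needed a score of at least 1, a margin of 0.5 and 3 markers detected in at least 10% of the cluster's cells. The margin was not needed between 2 trophoblast lists. A cluster whose best list was a trophoblast list with a score above 0 but under 1 was called trophoblast-like without a subclass. This held for clusters 12 (0.687) and 25 (0.646), and not for cluster 16 (-0.0102). Of 47 clusters, 43 were named in this way, and classes are called "-like" for this reason. Cluster 31, named fetal mesenchyme-like by score, has a smooth muscle marker and none of its own among its 10 leading genes, so it is given only by number. Marker genes describe a class and are not evidence of a difference within it.

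UMIs were summed over the cells of a class, given as CPM and compared where a class had at least 100 cells in both libraries. In a ratio, a count under 3 was set to 3. Ratios carry 95% intervals from the counts of the gene. Libraries on neighbouring days were compared, and E12.5 with E7.5, with no test because each day has 1 library. The named genes were fixed by rule: the 10 highest and 10 lowest ratios among genes with at least 100 CPM in the higher library and 50 UMIs over both. Mitochondrial, ribosomal protein, Xist, Y-linked and unnamed gene models were left out. Of each of 19 fixed gene lists, the up to 4 most abundant members were named, and any with a ratio over 4 in either direction at 20 CPM or more. A list's median log2 ratio over members with at least 20 UMIs was placed among 10000 random lists matched on level in 20 bins. Percentiles between 2.5 and 97.5 are called the central range. Free RNA was read from T-like and B-like cells together, called lymphocyte-like.

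The interval method was tested on simulated data, with counts of 50 genes per fold changed in the E12.5 over E7.5 trophoblast-like sums. The intervals held the true fold for 94, 96, 92 and 92% of genes at folds of 2, 4, 0.5 and 0.25, and the naming rule, which takes up to 10 genes per direction, named 10 of the 50 genes at 4 and 10 of the 50 at 0.25. It named 0 of the 50 genes at folds of 2 and 0.5, but the genes at 4 and 0.25 filled all 10 places per direction. Smaller differences can therefore go unnamed where larger ones exist, and how often this happens was not measured. A planted list of 12 genes at a fold of 2 reached percentile 100, and 4 of 100 random lists fell outside the central range. The simulated counts were Poisson draws around 1 shared set of levels, so these checks cover counting error and not differences between libraries.

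Comparisons, filters, gene lists, markers and most alternatives were chosen before the data were examined. The alternatives were other filters, no doublet removal, other clustering settings, a class per cell, clustering per library, TMM scaling with edgeR 4.0.16 under R 4.3.3, CPM without abundant families, equal weights for cells, thinning to 2000 UMIs and other minimums. Counting cluster 16 as trophoblast-like, leaving out clusters 12 and 25 and using all kept cells for gene levels were chosen after seeing the data. Work ran under Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.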

Results

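The mouse placenta is built by trophoblast, fetal blood, vessels and mesenchyme, and maternal decidua and immune cells. The comparisons here ask which of these classes, and which of their genes, differed between placentas of CD1 mice collected at E7.5, E8.5, E10.5, E11.5 and E12.5. Each day is represented by 1 library of cells pooled from several placentas, per the labels' protocols. Differences are therefore differences between libraries, and a day and its library cannot be separated. No test between days, error between animals or count of changed genes could be given, and a trend over the 5 days was not tested. Values are stated with 95% intervals that cover counting error only, exact Poisson intervals for CPM (counts per 1e6 UMIs of a class) and exact binomial intervals for shares. No paired analysis was possible because each day has 1 pooled library.

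The 5 libraries held 13937, 11676, 9456, 15491 and 12482 barcodes in the order of days, of which 9935, 8530, 5521, 12511 and 9858 were kept. Their totals were 142343162, 106320606, 65322579, 156145305 and 122849059 UMIs. Kept cells had a median of 3419, 3663, 6223, 5785 and 4006 UMIs and 1.87, 2.43, 2.09, 0.392 and 0.132% mitochondrial UMIs. Doublets were removed by score: 1131, 698, 615, 523 and 247 cells. The share of cells that survive dissociation was not measured, so a class share describes the suspension and not the tissue.

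The trophoblast-like cells of the 5 libraries were of different kinds. The E7.5 and E8.5 libraries held parietal giant cell-like cells, the invasive giant cells next to the decidua (defined by Prl3d1, Prl4a1 and Hand1), and cells like the stem cell-bearing extraembryonic ectoderm. The E11.5 and E12.5 libraries held many cells named spongiotrophoblast-like from a marker list (with Tpbpa, Tpbpb and Prl8a9), after the layer that supports the labyrinth. Most of these cells were of cluster 0, and fewer of cluster 26, which has Psg genes among its leading genes. The size of this class therefore rests mainly on the naming of cluster 0 by score. Cluster 0 scored 1.41, with 5 of the 6 markers detected but none of them among its 10 leading genes. Glycogen trophoblast-like cells, named after cells that store glycogen and later enter the decidua, were found in all 5. At E7.5 and E8.5 nearly all were of cluster 6 (1442 and 444 cells), where 3 of the 6 markers of the class were detected. Whether those cells store glycogen was not measured. Syncytiotrophoblast-like cells, the exchange layer, made up their largest share at E12.5.

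Trophoblast-like cells of all kinds made up 45.1% (44.1 to 46.0) of 9935 kept cells at E7.5, 28.7% (27.8 to 29.7) of 8530 at E8.5 and 19.1% (18.1 to 20.2) of 5521 at E10.5. They made up 33.9% (33.1 to 34.8) of 12511 at E11.5 and 50.7% (49.7 to 51.7) of 9858 at E12.5. With globin, prolactin-family, pregnancy-specific glycoprotein and cell cycle genes left out of the clustering, these shares were 46.5, 29.2, 22.3, 38 and 56.9%. Parietal giant cell-like cells made up 11.4, 18.3, 1.76, 0.615 and 0.396% in the order of days. Under some settings E7.5 was above E8.5 instead (23.4 and 22% with a minimum of 1000 genes), so the order of these 2 days is open. Spongiotrophoblast-like cells made up 0, 0, 2.52, 16.6 and 32.1%, where 0 cells allow up to 0.0302% at E7.5 and 0.0352% at E8.5. At resolution 2 they made up 5.36% at E11.5, and with each library clustered on its own 14.2% at E12.5, so the size of the class depends on the clustering. Glycogen trophoblast-like cells made up 14.5, 5.40, 9.64, 13.4 and 9.42%, but 1.15, 1.77, 4.15, 10.7 and 6.31% at resolution 2, so the high share at E7.5 depends on the clustering. Syncytiotrophoblast-like cells made up 0.382, 0.0703, 2.41, 1.2 and 6.11%. Stem/extraembryonic ectoderm-like cells made up 7.03, 2.40, 0.525, 0.296 and 0.0609%. Trophoblast-like cells without a subclass made up 11.7, 2.57, 2.26, 1.89 and 2.65%, and 84.4% of their cluster 12 came from the E7.5 library, so that cluster is not read as a cell type.

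NK-like and macrophage-like cells were most frequent at E8.5 and fetal blood from E10.5 on. NK-like cells, the granzyme-rich lymphocytes of the decidua, made up 0.896, 18.3, 7.92, 2.09 and 1.77% in the order of days. Macrophage-like cells made up 5.59, 13.8, 9.29, 2.28 and 2.34%. Erythroid-like cells, defined by globins, made up 0.0302 and 0.0234% at E7.5 and E8.5 and 18.2, 21.6 and 16.9% at E10.5, E11.5 and E12.5. Haematopoietic progenitor-like cells were most frequent at E10.5 (14.3%, against 0.141% at E8.5 and 4.10% at E11.5), as were megakaryocyte-like cells (4.93%, against 0 and 0.711%). Decidual stroma-like cells made up 0.312, 5.03, 2.70, 1.61 and 0.304%, endothelial-like cells 1.75, 4.88, 3.75, 2.72 and 0.964%. Under 4 other settings hardly any cells were named endothelial-like from E10.5 on (0.0365% at E10.5 with a mitochondrial maximum of 10%), so the later class rests on the setting. Epiblast and primitive streak-like cells, which belong to the embryo proper, made up 19.3% at E7.5 and 5.46% at E8.5, and at most 0.127% later, but only 6.19% at E7.5 with the gene families left out of the clustering. With each library clustered on its own they made up 0% at E8.5. Visceral endoderm-like cells, from the yolk sac lineage, made up 9.30, 3.62, 1.94, 1.34 and 0.822%. Parietal endoderm-like cells, which lay down Reichert's membrane, made up 5.22, 0.492, 0.797, 4.97 and 2.15%. Other immune classes were most frequent as follows: T-like cells at E10.5 (7.46%), neutrophil-like at E11.5 (7.93%), dendritic-like at E12.5 (3.72%) and B-like at E8.5 (6.89%). With a minimum of 200 genes B-like cells were most frequent at E10.5 instead (9.01%, against 6.48% at E8.5). With 1000 genes T-like cells were most frequent at E12.5 (2.68%) and neutrophil-like at E8.5 (1.65%), so the days of these classes depend on the filter.

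**Figure D1:**
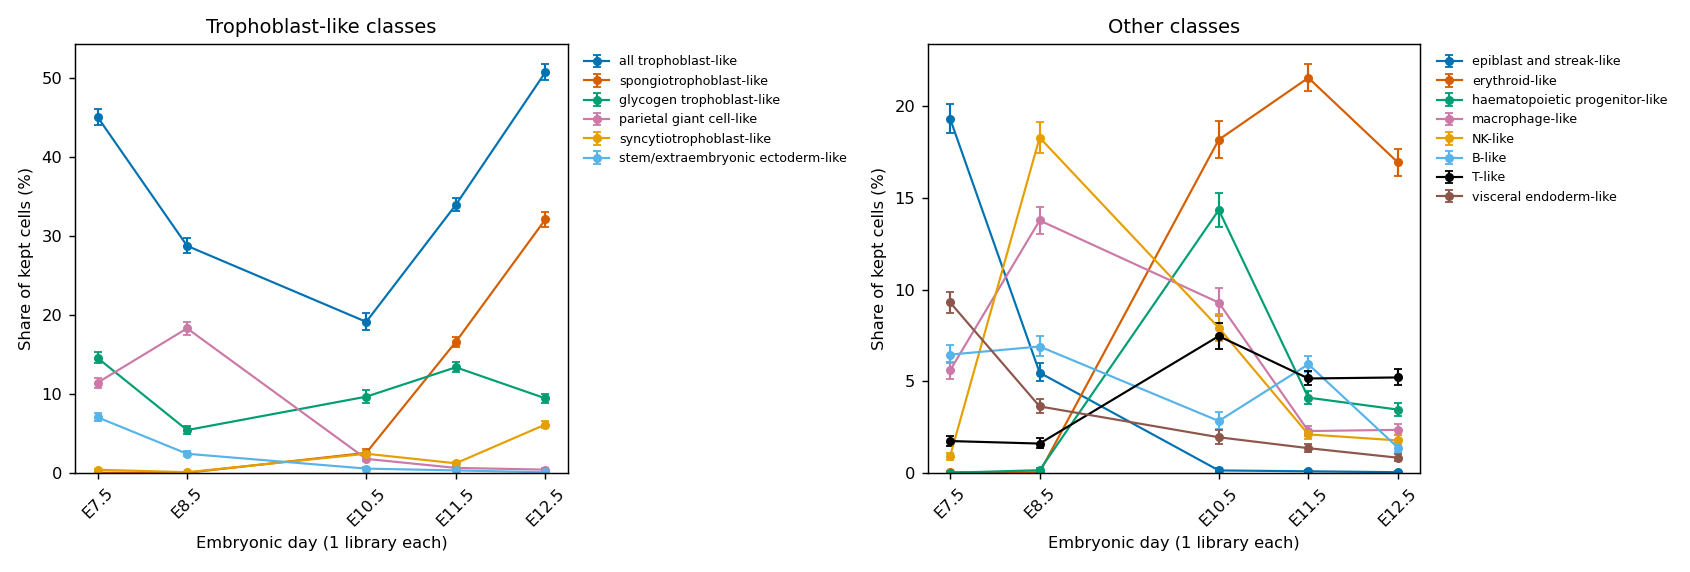
Share of kept cells (%) in selected classes by embryonic day, 1 library per day and points joined by lines, with exact 95% binomial intervals. Spongiotrophoblast-like cells made up 0% at E7.5 and 32.1% at E12.5, and erythroid-like cells at most 0.0302% before E10.5 and between 16.9 and 21.6% from then on.

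Trophoblast-like cells carried more RNA of several hormone and steroid genes at E8.5 than at E7.5. Prl2c1 and Prl7d1, hormones of the prolactin family of which Prl7d1 acts against vessel growth, were both higher. Cyp11a1, whose enzyme starts steroid synthesis from cholesterol, was higher as well. Id2, an inhibitor of differentiation, the S-phase histone Hist1h1b and the hexokinase Hk2 were lower, and so were the lists of stem factors and cell cycle genes. The mix of trophoblast classes differed between the libraries, and these levels mix the classes. The imprinted growth restrictors Cdkn1c and Phlda2 were higher, but imprinted genes were higher in neutrophil-like cells too, so this is not read as a trait of trophoblast.

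Prl2c1 (chromosome 13, 27849342 to 27857788, all positions on mm10) was 47.6-fold (41.7 to 54.5) higher, at 4.4 (3.85 to 5.01) CPM at E7.5 and 209 (204 to 215) at E8.5. Prl7d1 (chromosome 13, 27706337 to 27716736) was 14.8-fold (14.4 to 15.2) higher (114 and 1689 CPM, with 1.43 and 68.9 in lymphocyte-like cells, read as free RNA). The reductase gene Cyb5r3 was 4.18-fold (4.02 to 4.34) higher (72.7 and 304 CPM, with 44.9 and 56.3 in lymphocyte-like cells). Hist1h1b stood at a ratio of 0.204 (0.192 to 0.217), from 188 and 38.4 CPM, Hk2 at 0.232 (0.216 to 0.248) and Id2 at 0.339 (0.325 to 0.354). In all kept cells without classes, Id2 went the other way. Of the prolactin family, 16 of 21 measured members were higher (median 1.32, percentile 100, log2 and among random matched lists throughout). Steroid and prostaglandin genes were higher in 7 of 8 (median 1.81, percentile 100), with Cyp11a1 at 154 and 434 CPM. Imprinted genes were higher in 17 of 22 (median 0.45, percentile 100), with Cdkn1c at 1763 and 2772 CPM (139 and 224 in lymphocyte-like cells) and Phlda2 at 1095 and 1898 (93.4 and 145). In neutrophil-like cells imprinted genes were higher in 11 of 11 (median 1.15, percentile 100) and the prolactin family in 7 of 9 (median 0.72, percentile 98.7), so free RNA or a difference of the whole library was not excluded. In cluster 20, of parietal giant cell-like cells, the prolactin family was lower in 10 of 16 (median -0.57, percentile 0), so its direction depends on the cluster. Extracellular matrix genes were higher in 9 of 12 (median 0.68, percentile 100), placental cathepsins in 4 of 5 (median 2.96, percentile 100), placental Ceacam in 2 of 2 (median 2.67, percentile 99.9) and angiogenic factors in 8 of 14 (median 0.47, percentile 99.9). In parietal giant cell-like cells cathepsins were lower in 2 of 3 (median -0.31; within cluster 8 -1.45 and within cluster 20 -1.68), so their direction depends on the class. Every one of 11 stem and progenitor factors was lower (median -1.32, percentile 0), among them Tfap2c (413 and 299 CPM) and Ets2 (251 and 129). Cell cycle genes were lower in 19 of 21 (median -0.37, percentile 0.13), hypoxia and glycolysis genes in 12 of 15 (median -0.40, percentile 0.26) and glycogen metabolism genes in 7 of 9 (median -0.42, percentile 1.63). Neutrophil-like cells moved by about as much in hypoxia and glycolysis (11 of 14 lower, median -0.34) and glycogen metabolism (3 of 4, -0.44), and by more in angiogenic factors (2 of 3 higher, 1.35), so these lists are not read as traits of trophoblast. The 3 placental lactogen I genes were all lower (median -1.33, percentile 0.020) but all higher in glycogen trophoblast-like cells (median 2.44, percentile 100), so their direction depends on the class, while placental lactogen II, Prl3b1, was higher (2.42 and 52.3 CPM). Lists near the middle were differentiation factors (median -0.30), transporters (0.01), pregnancy-specific glycoproteins (0.14), niche signals (0.24), stress genes (-0.28) and antiviral genes (-0.06). Prl3d1, which defines the parietal giant cell-like class, was lower by summed UMIs and higher with cells weighed equally, so its direction between these libraries depends on how cells are weighed. Parietal giant cell-like cells were 1133 of 4477 trophoblast-like cells at E7.5 and 1560 of 2451 at E8.5, and stem-like cells 698 and 205. Stem factors were lower in 7 of 8 in glycogen trophoblast-like cells (median -0.93, percentile 0.050) and in 7 of 11 in parietal giant cell-like cells (median -0.28, percentile 8.96). In the latter the mix of clusters 8 (557 and 1250 cells) and 20 (576 and 309) differed, and within each the list was lower (median -0.49, percentile 1.21, and median -0.43, percentile 1.61).

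In trophoblast-like cells Thbd, which encodes the anticoagulant receptor thrombomodulin, the junction gene Jam3 and the matrix gene Ecm1 were lower at E10.5 than at E8.5. The steroid gene Cyp11a1 was lower too. So were the glycolytic genes Ldha and Gapdh, but also in neutrophil-like and lymphocyte-like cells, so they are not read as a trait of trophoblast. Placental lactogen II (Prl3b1), the imprinted zinc finger gene Peg3 and Kitl, the ligand that keeps blood stem cells and mast cells alive, were higher. Within glycogen trophoblast-like cells Prl3b1 was lower, so its direction depends on the class.

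Jam3 stood at a ratio of 0.0231 (0.016 to 0.0323), at 119.8 and 2.77 CPM, Thbd at 0.029 (0.0217 to 0.038), at 149 and 4.32 CPM and Ecm1 at 0.0416 (0.0318 to 0.0535). Prl3b1 (chromosome 13, 27241847 to 27249683) was 10.9-fold (10.4 to 11.6) higher (52.3 and 572 CPM, with 0 and 40.1 in lymphocyte-like cells). In glycogen trophoblast-like cells it was lower (log2 ratio -1.80). Kitl was at 6.12 and 78.5 CPM and Peg3 at 93 and 492. Cox17, Tomm7, Anapc13 and Pdcd4 were also among the highest ratios, but lymphocyte-like cells of the same libraries moved with them (Tomm7 165 and 936 CPM, against 109 and 471). Of the prolactin family, 16 of 21 were lower (median -2.08, percentile 0), as were 12 of 13 angiogenic factors (median -1.52, percentile 0) and 7 of 8 steroid and prostaglandin genes (median -1.85, percentile 0), with Cyp11a1 at 434 and 51.4 CPM. Hypoxia and glycolysis genes were lower in 12 of 15 (median -0.93, percentile 0), with Ldha at 1354 and 493 CPM (519 and 224 in lymphocyte-like cells) and Gapdh at 2401 and 1277 (1099.7 and 637), and by as much in neutrophil-like cells (11 of 11, median -0.92, percentile 2.08). Stem and progenitor factors were lower in 9 of 11 (median -1.55, percentile 0), the 3 placental lactogen I genes in all (median -2.89, percentile 0.090), niche signals in 5 of 7 (median -2.24, percentile 0.010), but not in glycogen trophoblast-like cells (2 of 3 higher), and differentiation factors in 6 of 11 (median -0.74, percentile 0.83), where Pparg ran the other way (10.9 and 44.7 CPM). Placental Ceacam genes were higher in 5 of 6 (median 5.39, percentile 100) and placental cathepsins in 4 of 6 (median 3.59, percentile 100), with free RNA not excluded, since neutrophil-like cells gave medians of 5.05 and 1.60. Within glycogen trophoblast-like cells 2 of 4 Ceacam genes (median 0.53) and 3 of 6 cathepsins (median -0.05) were higher, and both lists lay inside the central range. T-like cells moved with the prolactin family (-2.58) and angiogenic factors (-2.47). Neutrophil-like cells went the other way (10 of 12 higher, median 2.81, and 2 of 3 higher, median 0.28). Matrix genes (0.27), transporters (-0.13), imprinted genes (-0.16), pregnancy-specific glycoproteins (-0.23), glycogen metabolism (-0.33), cell cycle (-0.07), stress (-0.04) and antiviral genes (-0.08) had medians inside the central range. The class mix differs between these libraries (parietal giant cell-like cells were 1560 of 2451 trophoblast-like cells at E8.5 and 97 of 1055 at E10.5), and the levels mix these classes.

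At E11.5 Flt1, whose soluble form binds VEGF, and Rarres2, the chemokine chemerin, were higher in trophoblast-like cells than at E10.5. Matrix genes such as Sparc were higher too, but also in erythroid-like cells, so they are not read as a trait of trophoblast. Psg and placental Ceacam genes, secreted proteins of the spongiotrophoblast, were higher in every measured member, and cell cycle genes were lower. Erythroid-like cells moved with both, so free RNA or a difference of the whole library was not excluded.

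Flt1 (chromosome 5, 147561604 to 147726011) was 24.3-fold (20.3 to 29.3) higher, at 9.85 (8.18 to 11.8) CPM at E10.5 and 239 (235 to 243) at E11.5, and Rarres2 17.2-fold (14.1 to 21.3) higher (7.82 and 135 CPM, with 2.86 and 29.6 in lymphocyte-like cells). Snrpg, Bola2 and Polr2l were lower, but also in lymphocyte-like cells (Snrpg 910.2 and 340.2 CPM, against 399.9 and 230.5). Matrix genes were higher in 11 of 12 (median 1.89, percentile 100), with Sparc at 267 and 1138 CPM (41 and 141 in lymphocyte-like cells), Fn1 at 44.9 and 209.6 (2.86 and 9.25) and Col4a1 at 28.3 and 168 (0.954 and 22.2). They were higher in 8 of 9 in erythroid-like cells (median 1.79, percentile 100) but only in 3 of 8 in spongiotrophoblast-like cells. Parietal endoderm-like cells, rich in Sparc, numbered 44 at E10.5 and 622 at E11.5, so free RNA was not excluded as a part of the difference. Psg genes were higher in 12 of 12 (median 4.02, percentile 100), placental Ceacam in 7 of 7 (median 3.46, percentile 100), placental cathepsins in 6 of 6 (median 2.23, percentile 100), the prolactin family in 16 of 24 (median 1.84, percentile 100) and angiogenic factors in 8 of 11 (median 0.74, percentile 99.2). Glycogen metabolism genes were higher in 8 of 10 (median 0.53, percentile 98.2), with Ugp2 at 119 and 202 and Pgm1 at 36.6 and 104 CPM, and Prl3b1 was higher (572 and 1835 CPM). Cell cycle genes were lower in 20 of 21 (median -0.33, percentile 0.090), transporters in 12 of 20 (median -0.27, percentile 1.33), imprinted genes in 13 of 21 (median -0.37, percentile 0.58), with Phlda2 at 1188 and 542 CPM, and steroid and prostaglandin genes in 4 of 7 (median -0.65, percentile 0.725), although Cyp17a1 was higher (20.4 and 53.9 CPM). Within classes some of these lists went the other way: steroid and prostaglandin genes were higher in 6 of 6 in glycogen trophoblast-like cells (median 1.26, percentile 99.3), transporters in 8 of 9 in spongiotrophoblast-like cells, and cell cycle genes in 19 of 21 in syncytiotrophoblast-like cells. The prolactin family was lower in 13 of 21 in spongiotrophoblast-like cells. The 3 placental lactogen I genes were lower (median -2.60, percentile 0.010). Hypoxia and glycolysis genes (0.35), differentiation factors (0.11), stem factors (-0.05), niche signals (-0.40), stress genes (-0.05) and antiviral genes (0.38) lay inside the central range. In erythroid-like cells Psg genes were higher in 8 of 8 (percentile 100), placental Ceacam in 7 of 7 (median 3.45, percentile 100), cathepsins in 5 of 5 and the prolactin family in 12 of 17, and cell cycle genes were lower in 21 of 21. In T-like cells angiogenic factors were higher in 4 of 4. The class mix again differed, with 139 spongiotrophoblast-like cells at E10.5 and 2073 at E11.5, and the median gene was 0.10 log2 higher in CPM.

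In trophoblast-like cells the glucose transporter Slc2a1 and the amino acid transporter Slc38a4 were higher at E12.5 than at E11.5, as were the imprinted genes Phlda2 and Cdkn1c. Hbegf, an EGF-family ligand of trophoblast invasion, and Baiap2l1, which bends membranes at actin-rich protrusions, were higher. Plac8, a gene of glycogen trophoblast and decidua, was lower, and so were matrix genes such as Sparc, here and in erythroid-like cells. Hsd11b2, whose enzyme inactivates glucocorticoids at the placental barrier, was higher, in part because more of the cells were syncytiotrophoblast-like.

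Baiap2l1 was 5.83-fold (5.56 to 6.13) higher (38 and 222 CPM, with 4.07 and 38.4 in lymphocyte-like cells) and Hbegf 4.9-fold (4.61 to 5.21) higher (25.3 and 124 CPM). Plac8 stood at 0.383 (0.38 to 0.386), at 4749.7 and 1818 CPM and with 715 and 264 in lymphocyte-like cells, and the serpin gene Serpinb9f at 0.376 (0.36 to 0.392). Tpm3-rs7 was higher, but it is a near copy of Tpm3 whose reads it can share, and lymphocyte-like cells moved with it (4.44 and 195 CPM). Transporters were higher in 17 of 20 (median 0.59, percentile 100), with Slc2a1 at 115 and 305 and Slc38a4 at 134 and 239 CPM, and in 13 with TMM scaling. Within glycogen trophoblast-like cells 15 of 18 transporters were higher. Within syncytiotrophoblast-like cells only 9 of 20 were higher (median 0.01 with TMM scaling), so the difference does not hold in every class. Cell cycle genes were higher in 20 of 21 (median 0.52, percentile 100), but lower in 18 of 21 in spongiotrophoblast-like cells, the largest trophoblast class. Psg genes were higher in 10 of 12 (median 1.48, percentile 100) and placental Ceacam in 5 of 7 (median 0.91, percentile 100), while the prolactin family was lower in 16 of 24 (median -1.34, percentile 0), though not within spongiotrophoblast-like cells (median 0.27). In cluster 26 of that class, with 102 cells at E11.5 and 445 at E12.5, the family was lower in 10 of 18 (median -0.29, percentile 0.87). The exception therefore does not hold in every cluster. Matrix genes were lower in 11 of 14 (median -0.79, percentile 0), with Sparc at 1138 and 634 CPM (141 and 86.8 in lymphocyte-like cells), and in 8 of 9 in erythroid-like cells. Also lower were angiogenic factors in 9 of 12 (median -0.59, percentile 0.020), antiviral genes in 7 of 13 (median -0.13, percentile 1.21) and the 3 placental lactogen I genes in all (median -4.06, percentile 0). Phlda2 was at 542 and 1653 CPM, Cdkn1c at 2570.1 and 4307 and Hsd11b2 at 4.78 and 63.3. Syncytiotrophoblast-like cells, in which Hsd11b2 was 3.12-fold (2.74 to 3.58) higher, were 150 of 4244 trophoblast-like cells at E11.5 and 602 of 5000 at E12.5, and the levels mix the classes. Imprinted genes as a list had a median of 0.15, which turned to -0.04 with TMM scaling, as cathepsins (0.07) turned to -0.11 and glycogen metabolism (0.08) to -0.10. Prl3b1 (0.30), differentiation factors (0.42), stem factors (0.32), niche signals (0.39), steroid genes (-0.00), hypoxia and glycolysis (-0.05) and stress genes (0.31) lay inside the central range. The median gene was 0.19 log2 higher at E12.5 than at E11.5 in CPM, and TMM scaling lowered all values by that much. Prl3b1 was lower at E12.5 where each library was clustered on its own. Erythroid-like cells moved with the Psg (10 of 11 higher) and Ceacam (5 of 7) genes, and neutrophil-like cells with the prolactin family (9 of 13 lower), angiogenic factors (3 of 3) and antiviral genes (10 of 13), so free RNA or a difference of the whole library was not excluded for these lists.

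Across the whole span, from E7.5 to E12.5, the placental lactogens stood in opposite order. Prl3d1, placental lactogen I of the parietal giant cells, and Prl3b1, placental lactogen II of later trophoblast, both bind the maternal prolactin receptor, and the early one was abundant only early. Flt1 and the matrix genes Sparc and Fn1 were higher at E12.5. Cyp11a1, Ldha, Hk2 and the glucose transporter Slc2a3 were lower. Kitl and the imprinted genes Peg3 and Peg10, the latter needed for the placental labyrinth, were higher.

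Prl3d1 (chromosome 13, 27094190 to 27100258) was at 1622 (1611 to 1633) CPM in trophoblast-like cells at E7.5 and 2.72 (2.25 to 3.26) at E12.5, a log2 ratio of -9.22, and Prl3b1 at 2.42 (2.02 to 2.88) and 2260.3 (2246 to 2274), a log2 ratio of 9.87. In all kept cells without classes, Prl3d1 was at 689 and 1.13 CPM and Prl3b1 at 1.11 and 925. Flt1 was at 7.52 and 192 CPM, Kitl at 5.54 and 90.4, Peg3 at 78.7 and 701 and Peg10 at 163 and 749. Cyp11a1 was at 154 and 3.25 CPM, Ldha at 1517 and 604, Hk2 at 129 and 10.7 and Slc2a3 at 58.1 and 0.646. Matrix genes were higher in 11 of 13 (median 1.82, percentile 100), with Fn1 at 8.19 and 194 and Sparc at 179 and 634 CPM, although Sparc was lower in all kept cells, and transporters in 15 of 20 (median 0.83, percentile 99.8). Psg (10 of 12 higher, median 9.09), placental Ceacam (6 of 7, 11.46) and placental cathepsins (5 of 7, 10.25) had medians set partly by members at the floor of 3 counts at E7.5. The 3 placental lactogen I genes were all lower (median -10.50, percentile 0), as were 10 of 11 stem and progenitor factors (median -1.29, percentile 0), 12 of 15 hypoxia and glycolysis genes (median -0.87, percentile 0.010), 15 of 21 cell cycle genes (median -0.39, percentile 0.99), 8 of 13 antiviral genes (median -0.42, percentile 1.81) and 6 of 12 stress genes (median -0.44, percentile 1.9). The prolactin family was divided (12 higher and 12 lower, median -0.04), and imprinted genes (0.24), angiogenic factors (-0.25), niche signals (0.29), steroid genes (0.33), glycogen metabolism (-0.24) and differentiation factors (-0.35) lay inside the central range. In B-like cells hypoxia and glycolysis (11 of 11 lower), cell cycle (11 of 12), antiviral (10 of 10) and stress genes (9 of 12) went the same way, so these lists are not read as traits of trophoblast. The class mix differed, with 1133 parietal giant cell-like cells at E7.5 and 39 at E12.5, and 0 and 3163 spongiotrophoblast-like cells. In CPM the median gene was 0.21 log2 higher.

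**Figure D2:**
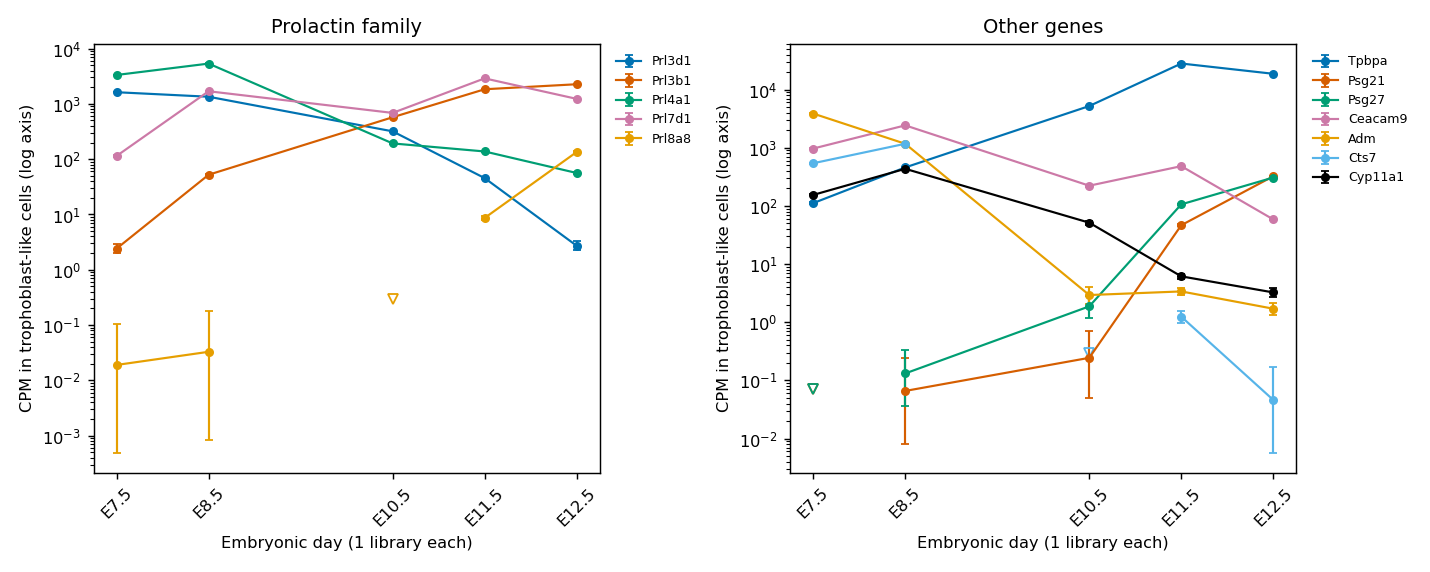
Level (CPM, log axis) of genes in trophoblast-like cells by embryonic day, 1 library per day, with exact 95% Poisson intervals and open triangles at the upper bound where no UMI was found. Prl3d1 was at 1622 CPM at E7.5 and 2.72 at E12.5, and Prl3b1 at 2.42 and 2260.3.

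Within glycogen trophoblast-like cells, prolactin-family hormones marked the E8.5 library. Prl7d1, Prl2c1 and Sult1e1, an estrogen sulfotransferase, were higher at E8.5 than at E7.5, and Hk2, Slc2a1 and the lactate exporter Slc16a3 were lower. At E10.5 the same prolactin genes were far lower, and so were Ugp2 and Pgm1, which make the precursor of glycogen. At E11.5 Flt1 and Tnfrsf9, a costimulatory receptor, were higher. At E12.5 the cell cycle list was higher in every measured member.

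Prl7d1 was 16.5-fold (16 to 16.9) higher at E8.5 (607 and 10012 CPM), Prl2c1 58.8-fold (51.2 to 67.8) and Sult1e1 19.6-fold (16 to 24.3), and all 20 measured prolactin genes were higher (median 3.0, percentile 100, against 0.72 in neutrophil-like cells). Hk2 stood at 0.176 (0.153 to 0.202), with Slc2a1 at 383 and 98.3 CPM and Slc16a3 at 139 and 33.2, while the lists of hypoxia and glycolysis (-0.32) and glycogen metabolism (-0.50) lay inside the central range. From E8.5 to E10.5 the prolactin family was lower in 19 of 20 (median -5.16, percentile 0) and glycogen metabolism in 8 of 9 (median -1.16, percentile 0.020), with Ugp2 at 225 and 88.1 and Pgm1 at 141 and 41.7 CPM. At E11.5 Flt1 was 38.7-fold (30.2 to 50.4) higher than at E10.5, Tnfrsf9 6.95-fold (6.5 to 7.44) and Prl3b1 13.7-fold (12.8 to 14.7), while Phlda2 stood at 0.224 (0.215 to 0.234). Matrix genes were then higher in 10 of 10 (median 2.29, percentile 100), with Sparc at 335 and 1463 CPM (41 and 141 in lymphocyte-like cells) and Fn1 at 46.3 and 262 (2.86 and 9.25), as they also were in erythroid-like cells. Glycogen metabolism was higher in 8 of 10 (median 0.74, percentile 99.8). From E11.5 to E12.5 cell cycle genes were higher in 21 of 21 (median 0.59, percentile 100) and transporters in 15 of 18 (median 0.48, percentile 99.7), with Slc38a4 at 126 and 217 CPM, and Prl7d1 was lower (3129.7 and 1396 CPM). The class held 1445, 461, 532, 1671 and 929 cells with median UMIs of 2673, 4587, 13798, 13070.0 and 15235. Cluster 6 held most of them at E7.5 and E8.5 and clusters 10 and 11 later, so the step from E8.5 to E10.5 compares different clusters. The median gene was -0.17, 0.21, 0.13 and 0.21 log2 in CPM at these steps, and no direction given for a list of the whole class turned with TMM scaling. The levels after E10.5 mix clusters 10 and 11, which differed. Within cluster 11, with 870 cells at E11.5, Prl3b1 was lower at E11.5 (log2 ratio -0.51, against 4.63 in cluster 10). There matrix genes (median 0.45) and glycogen metabolism (0.38) lay inside the central range at E11.5. At E12.5 transporters (0.08) and cell cycle genes (0.23, 19 of 21 higher) did so too.

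Spongiotrophoblast-like cells could be compared from E10.5 on. Fabp5, a fatty acid carrier, was higher at E11.5. At E12.5 Creg1, a lysosomal glycoprotein, Baiap2l1 and Arhgap8, a Rho GTPase regulator, were higher, and the carbonic anhydrase gene Car2 was lower. Most Psg genes were higher at each step, as they were in erythroid-like cells.

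Fabp5 was 3.94-fold (3.05 to 5.17) higher at E11.5 (119 and 468 CPM, with 54.4 and 81 in lymphocyte-like cells). Psg genes were higher in 10 of 12 (median 1.35, percentile 100) at E11.5 and in 12 of 12 (median 1.62, percentile 100) at E12.5, Psg23 at 39.7 and 216 CPM. Creg1 was 4.44-fold (4.34 to 4.54) higher at E12.5 (1008 and 4475 CPM, with 96.6 and 326 in lymphocyte-like cells), Baiap2l1 5.72-fold (5.3 to 6.19) and Arhgap8 4.02-fold (3.58 to 4.53). Car2 stood at 0.307 (0.298 to 0.317), at 2093 and 643 CPM. Transporters were higher in 13 of 16 (median 0.56, percentile 100) and hypoxia and glycolysis genes in 11 of 14 (median 0.27, percentile 99.8), while cell cycle genes were lower in 18 of 21 (median -0.33, percentile 0.040) and imprinted genes in 13 of 17 (median -0.38, percentile 0.040). The class held 139, 2073 and 3163 cells in clusters 0 and 26, with median UMIs of 2390.0, 2951 and 1974. Cluster 26, with Psg genes among its leading genes, held 2, 102 and 445 of them, so the steps compare different mixes. Within it at E12.5 Psg genes were higher in 11 of 12 (median 0.79). The medians there were 0.09 for transporters, 0.11 for hypoxia and glycolysis and -0.03 for imprinted genes, inside the central range.

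Parietal giant cell-like cells held more steroid enzyme RNA at E8.5 than at E7.5. Cyp11a1 and Cyp17a1, which turn cholesterol into androgens, were higher, as were Klhl13, an adaptor for ubiquitin ligation, and the homeobox genes Rhox6 and Rhox9. Hk2 and the scaffold gene Akap12 were lower.

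Klhl13 was 12.8-fold (11.2 to 14.7) higher (8.91 and 114 CPM), Rhox9 6.64-fold (6.44 to 6.84) and Rhox6 5.5-fold (5.38 to 5.64), while Akap12 stood at 0.248 (0.229 to 0.268) and Hk2 at 0.229 (0.208 to 0.252). Steroid and prostaglandin genes were higher in 6 of 7 (median 1.40, percentile 100; 1.84 within cluster 8 and 0.54 within cluster 20), with Cyp11a1 at 225 and 596 CPM, and imprinted genes in 16 of 20 (median 0.65, percentile 100), less than in neutrophil-like cells (median 1.15). Niche signals were higher in 6 of 7 (median 1.34, percentile 99.8). The comparison covers 1133 and 1560 cells, mostly of clusters 8 (557 and 1250) and 20 (576 and 309), with median UMIs of 12822 and 4551.

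In syncytiotrophoblast-like cells Lpl, the lipase that frees fatty acids from lipoproteins, was higher at E11.5 than at E10.5, together with cell cycle genes. Hsd11b2 and the calcium-binding gene S100a16 were higher at E12.5 than at E11.5, and the metallothionein gene Mt1 was lower.

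Lpl was 3.09-fold (2.46 to 3.92) higher at E11.5 (42.7 and 132 CPM), and cell cycle genes were higher in 19 of 21 (median 0.61, percentile 100). Hsd11b2 (chromosome 8, 105518755 to 105523988) was 3.12-fold (2.74 to 3.58) higher at E12.5 (64.1 and 200.4 CPM, with 0.37 and 0 in lymphocyte-like cells) and S100a16 4.06-fold (3.52 to 4.71). Mt1 stood at 0.176 (0.164 to 0.189), and matrix genes were lower in 6 of 9 (median -1.39, percentile 0), as in erythroid-like cells. The class held 133, 150 and 602 cells, with median UMIs of 14138, 23122 and 15602, and the median gene was 0.27 log2 higher at E11.5.

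In stem/extraembryonic ectoderm-like cells, differentiation factors were higher at E8.5 than at E7.5. Esx1, a homeobox gene of the chorion and labyrinth, Wfdc2 and Gata2 were higher, and the homeobox gene Irx3 and the S-phase histone Hist1h2ae were lower. Stem factors were lower almost throughout.

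Esx1 was 7.14-fold (5.97 to 8.57) higher (16.8 and 119.6 CPM) and Wfdc2 6.74-fold (5.99 to 7.59), while Hist1h2ae stood at 0.0683 (0.0471 to 0.0959) and Irx3 at 0.27 (0.219 to 0.329). Stem and progenitor factors were lower in 10 of 11 (median -1.34, percentile 0), and differentiation factors were higher in 7 of 10 (median 0.70, percentile 99.9), Gata2 at 45.5 and 190.4 CPM. The class held 698 and 205 cells, with median UMIs of 4197 and 2890.0.

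Endothelial-like cells of E7.5 carried more RNA of a blood formation gene than those of E8.5. Runx1, required for the emergence of blood stem cells, was lower at E8.5, and Dlk1, Meg3, Plagl1 and Igfbp5, imprinted or IGF-pathway genes of growing fetal tissue, were higher. At E10.5 the class held more of Fabp4 and Cd36, fatty acid uptake genes of mature capillaries.

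Plagl1 was 81.9-fold (44.3 to 171) higher at E8.5 (1.79 and 146 CPM), Dlk1 57.1-fold (42.6 to 78.5) and Igfbp5 46.5-fold (29.3 to 78.9), while Runx1 stood at 0.0403 (0.0287 to 0.0551), at 176 and 7.11 CPM. Imprinted genes were higher in 20 of 22 (median 2.05, percentile 100, against 1.15 in neutrophil-like cells) and angiogenic factors in 11 of 13 (median 1.71, percentile 100, against 1.35 over 3 genes there). At E10.5 Chrdl1, a BMP antagonist, was 119.8-fold (63.9 to 248) higher than at E8.5, Fabp4 47.4-fold (26.7 to 88.9) and Cd36 46.3-fold (26.5 to 85.1), and hypoxia and glycolysis genes were lower in 14 of 14 (median -1.76, percentile 0), with Slc2a1 at 151 and 19.9 CPM, as they were in neutrophil-like cells (median -0.92). At E11.5 Flt1 was higher than at E10.5 (76.9 and 187 CPM). Clusters 35 (121 and 107 cells) and 37 (40 and 96) held cells of E7.5 and E8.5, cluster 22 held 213 of the E8.5 cells and most of the later ones, and the class had 174, 416, 207 and 340 cells with median UMIs of 28176, 3124, 1165 and 1300.5, so the steps compare different mixes of clusters at very different depth. The median gene was 0.19 log2 higher at E8.5 and 0.14 at E11.5.

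Globin made up more of the RNA of erythroid-like cells at each later day, and adult globin made up more of it at E12.5. The cells were of different clusters. Hba-x and Hbb-bh1, the embryonic zeta and beta-h1 chains, made up smaller shares of globin at E12.5 than at E10.5, and the adult beta genes Hbb-bs and Hbb-bt larger ones. Hbb-y, the embryonic epsilon-y chain, did not follow them and was highest at E12.5. Hmox1, which breaks down haem, was higher at E12.5 and cell cycle genes such as Mki67 were lower.

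Hbb-y, Hbb-bh1 and Hba-x made up 79.7% (79.6 to 79.7) of the UMIs of 7 globin genes at E10.5, 77.8% at E11.5 and 70.2% at E12.5, in 1004, 2698 and 1670 cells. Cluster 3 held 972 of them at E10.5, 1290 at E11.5 and 113 at E12.5, and cluster 2 held 11, 1148 and 1407. Within cluster 3 the embryonic share was 79.8, 79.9 and 74.9%, so the step from E10.5 to E11.5 was absent there, and within cluster 2 it was 75.4 and 69.9% at E11.5 and E12.5. Hba-x was 28.8, 19.5 and 8.95% of globin UMIs, Hbb-bh1 1.98, 0.651 and 0.217% and Hbb-y 48.9, 57.6 and 61.0%. Hbb-bs was 2.10, 5.35 and 7.92% and Hbb-bt 0.609, 0.785 and 1.89%. Adult chains made up 5.07, 9.54 and 13.8% of beta-type UMIs and 37.9, 45.2 and 69.1% of alpha-type UMIs. The 3 and 2 erythroid-like cells of E7.5 and E8.5 were too few to compare, and in T-like cells globin was 0.104, 0.558 and 1.11% of UMIs from E10.5 on, against 57.8, 72.7 and 82.9% in erythroid-like cells. Hmox1 was 4.29-fold (4.03 to 4.58) higher at E12.5 than at E11.5 (27.6 and 119 CPM, with 32.6 and 40.9 in lymphocyte-like cells) and Mki67 stood at 243 and 37.6 CPM. Tmem14c, a porphyrin transporter for haem synthesis, stood at 0.0805 (0.0755 to 0.0858), at 392 and 31.6 CPM with 90.6 and 75.2 in lymphocyte-like cells, and cell cycle genes were lower in 20 of 21 (median -2.02, percentile 0). The median gene was -0.90 log2 at E12.5 over E11.5 and -0.30 at E11.5 over E10.5, and TMM scaling added 0.80 and 0.33. With globin and other abundant families left out of the total it was -0.28 and 0.05, so the larger share of globin does not account for all of the first.

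**Figure D3:**
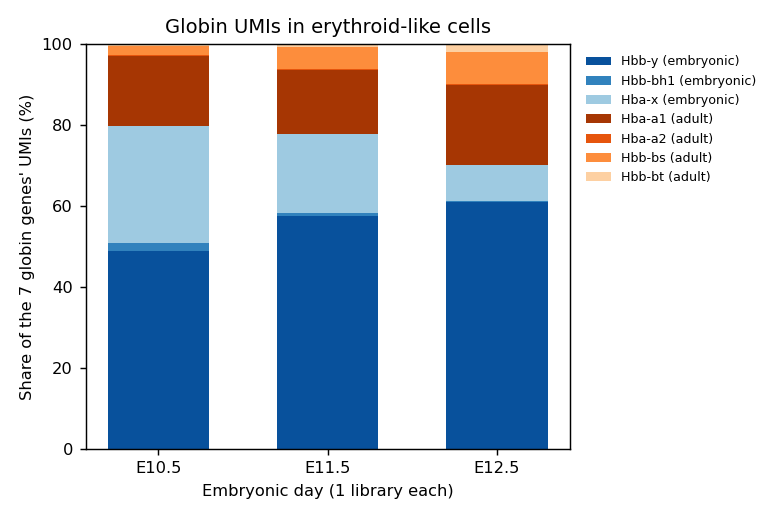
Share (%) of the UMIs of 7 globin genes from each gene in erythroid-like cells at E10.5, E11.5 and E12.5, 1 library per day. Embryonic globins together made up 79.7, 77.8 and 70.2%, and Hba-x 28.8, 19.5 and 8.95%.

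Decidual stroma-like cells were of different kinds at E8.5 and later. At E8.5 they held collagen (Col3a1) and the secretory-pathway gene Rcn1, and at E10.5 Procr, the protein C receptor, and the prostaglandin synthase Ptgds. At E11.5 the proteoglycan gene Dcn and the acute-phase gene Saa3 were higher.

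Procr was 145-fold (119 to 178) higher at E10.5 than at E8.5 (18.6 and 2691 CPM, the lower at the level of lymphocyte-like cells, 21.5 and 11.5), while Rcn1 stood at 0.00719 (0.00329 to 0.0137). Ptgds had 0 UMIs at E8.5 and was at least 528-fold higher at E10.5. Matrix genes were lower in 13 of 16 at E10.5 (median -3.14, percentile 0) and higher in 12 of 12 at E11.5 (median 2.07, percentile 100), with Dcn at 22.9 and 488 CPM (0 and 1.48 in lymphocyte-like cells). The list was higher in erythroid-like cells as well (8 of 9), so it is not read as a trait of the class. Antiviral genes were higher in 11 of 11 at E11.5 (median 1.66, percentile 100). Of the 429 cells at E8.5, 366 were in cluster 32, which is 99.2% from that library and so is not told apart from it, and cluster 28 held most of the 149 and 202 later cells. At E10.5 over E8.5 the median gene was -0.73 log2.

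Macrophage-like cells of E7.5 carried more RNA of interferon-response genes than those of E8.5 and E12.5, and so did neutrophil-like cells. The chemokines Ccl5 and Cxcl10 and the antiviral genes Rsad2 and Ifit1 were lower at E8.5, where the matrix gene Thbs1 and the neutrophil attractant Cxcl1 were higher. At E12.5 the cells held more Fn1, the complement gene C3 and Hpgd, which breaks down prostaglandins, than at E11.5. Over the whole span Acod1, an inflammatory enzyme that makes itaconate, was lower.

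Rsad2 stood at 0.213 (0.201 to 0.226) at E8.5 over E7.5, at 1657 and 353 CPM, Ccl5 at 0.163 (0.152 to 0.174) (with 61.3 and 319.9 CPM in lymphocyte-like cells, above the E8.5 macrophage-like level) and Cxcl10 at 0.214 (0.204 to 0.225), while Thbs1 was 4.46-fold (3.72 to 5.39) higher. Antiviral genes were lower in 11 of 13 at E8.5 (median -0.51, percentile 0.56), and in 11 of 13 in neutrophil-like cells (median -0.93, percentile 0.010). Arg2, an arginase, stood at 0.0966 (0.064 to 0.14) at E10.5 over E8.5, and Spp1, osteopontin, at 0.203 (0.159 to 0.258) at E11.5 over E10.5. At E12.5 Hpgd was 3.91-fold (2.77 to 5.63) higher than at E11.5 (44.6 and 175 CPM), and Fn1 was at 294 and 1028 CPM. Antiviral genes were lower in all 13 at E12.5 over E7.5 (median -2.16, percentile 0), with Isg15 at 3083 and 393 CPM, and in 10 of 12 in neutrophil-like cells (median -1.52, percentile 0), and Acod1 stood at 0.0528 (0.0271 to 0.0931). The class held 555, 1175, 513, 285 and 231 cells, mostly of cluster 1, with median UMIs of 3323, 4233, 1900.0, 3137 and 3272. In CPM, the median gene was -0.24 log2 at E10.5 over E8.5, 0.11 at E11.5 over E10.5 and -0.14 at E12.5 over E7.5.

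NK-like cells of E8.5 carried more RNA of cell cycle genes than those of E10.5. Pdia6 and Creld2, which fold proteins in the endoplasmic reticulum, and Srm, for polyamine synthesis, were lower at E10.5 too. At E12.5 the inhibitory receptor Klra8 was higher than at E8.5 and Ctla4 was lower. The mix of NK-like clusters differed between these libraries, and the levels mix the clusters.

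Pdia6 stood at 0.155 (0.136 to 0.175) at E10.5 over E8.5 and Srm at 0.205 (0.16 to 0.259). Cell cycle genes were lower in 18 of 21 (median -0.97, percentile 0.030), as in 18 of 20 in macrophage-like cells, and stress genes higher in 12 of 12 (median 1.96, percentile 100). At E11.5 over E10.5 antiviral genes were lower in 11 of 12 (median -1.19, percentile 0). Ctla4 stood at 0.0464 (0.0126 to 0.119) at E12.5 over E8.5. Of the 1561 cells at E8.5, 1018 were in cluster 13 and 420 in cluster 29, which is 95.7% from that library. Cluster 23, with Klra4, Klra1 and Ncr1 among its leading genes, held 123 of them at E8.5 and 255, 179 and 97 later. The steps therefore compare different mixes of clusters. The class held 437, 262 and 174 cells later, with median UMIs of 7182 at E8.5 and 2196, 1649.5 and 1839 later. At E12.5 over E8.5 the median gene was 0.45 log2.

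In visceral endoderm-like cells the monoamine oxidase gene Maob was higher at E10.5 than at E8.5, Emb, an adhesion gene, was lower, and Ahsg, the carrier protein fetuin, was higher at E11.5. In parietal endoderm-like cells the pepsinogen gene Pgc and Lbp, which binds bacterial lipopolysaccharide, were higher at E12.5 than at E11.5, and basement membrane genes such as Nid1 and Sparc were lower.

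Maob was 15.7-fold (11.3 to 22.4) higher at E10.5 than at E8.5 (24.4 and 385 CPM), and Emb stood at 0.0427 (0.0322 to 0.0556). Ahsg was 8.68-fold (4.48 to 19.3) higher at E11.5 than at E10.5. In parietal endoderm-like cells Pgc was 24.5-fold (20.2 to 30.1) higher at E12.5 (14.6 and 359 CPM) and Lbp 14.5-fold (11.5 to 18.6), while Nid1 stood at 0.236 (0.226 to 0.246). Matrix genes were lower in 8 of 9 (median -1.36, percentile 0.010), with Sparc at 31792 and 14133 CPM, and cell cycle genes were higher in 21 of 21 (median 1.03, percentile 100). Visceral endoderm-like cells were in cluster 15 early and cluster 33 late, and the classes held 924, 309, 107 and 168 visceral (E7.5 to E11.5) and 622 and 212 parietal cells (E11.5 and E12.5). The median gene was -0.46 log2 at E10.5 over E8.5 and 0.17 at E11.5 over E10.5 in the visceral class, and 0.11 in the parietal class.

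Y-linked RNA can mark classes that hold cells of male embryos, since the dam carries no Y chromosome. A class low in it can be maternal or come from female embryos, and this measure does not tell these apart. Ddx3y, Eif2s3y, Uty and Kdm5d were found in trophoblast-like, progenitor-like and erythroid-like cells and hardly in macrophage-like, NK-like, T-like and B-like cells. The sexes of the pooled embryos are not given in the sources used here.

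At least 1 UMI of these genes was present in 18.5, 23.8, 40.4, 24.4 and 15.4% of trophoblast-like cells in the order of days, with 0.489, 0.607, 0.847, 0.586 and 0.530 UMIs per 10000. Haematopoietic progenitor-like cells held them in 73.0, 60.2 and 42.9% from E10.5 on and erythroid-like cells in 30.3, 24.6 and 13.2%. Macrophage-like cells, taken as maternal background without a test of their origin, held them in 0.901, 1.53, 0.195, 0.702 and 2.16%. Their median UMIs were 3323, 4233, 1900.0, 3137 and 3272, against 3228, 4207, 5703, 4522 and 2577 in trophoblast-like cells. In decidual stroma-like cells at E8.5 the share was 1.40%. With each cell thinned to 2000 UMIs, trophoblast-like cells held them in 7.51, 10.1, 14.9, 9.49 and 8.60%, with 1599, 697, 221, 1020 and 1987 shallower cells left out.

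**Figure D4:**
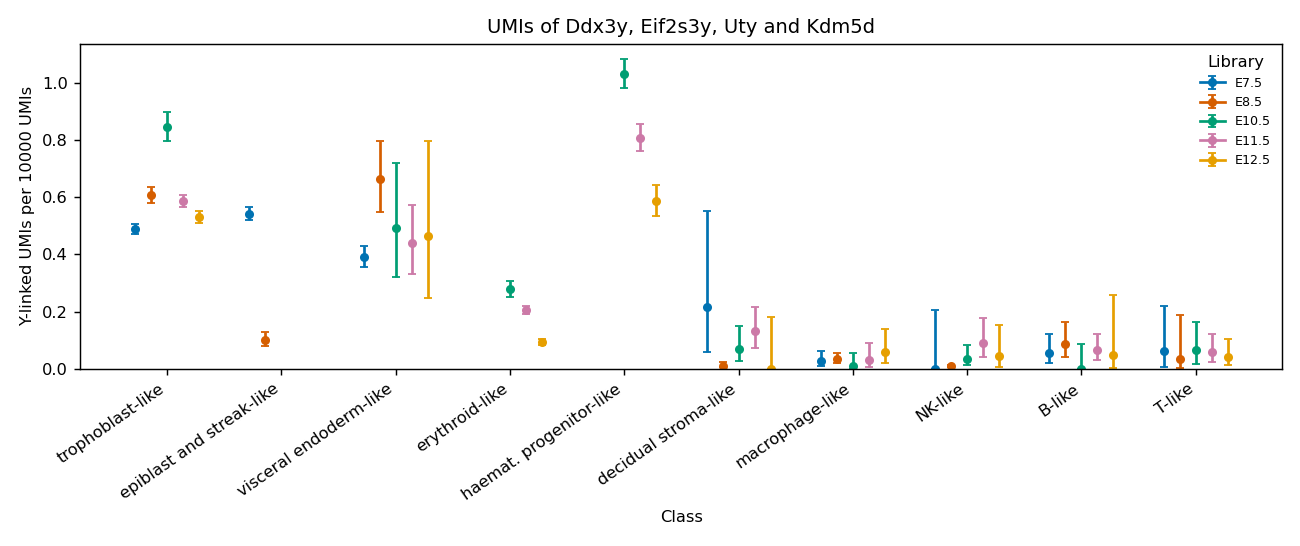
UMIs of Ddx3y, Eif2s3y, Uty and Kdm5d per 10000 UMIs in selected classes, 1 point per class and library, with exact 95% Poisson intervals. Trophoblast-like cells lay between 0.489 and 0.847 and macrophage-like cells between 0.00965 and 0.0594.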

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

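The share of trophoblast-like cells moved beyond its counting interval under most settings, and the cause was not tested for any of them. With a minimum of 200 genes it was 42% at E7.5, 13.8% at E10.5 and 32.5% at E11.5, and with 1000 genes 31.1% at E8.5, 25% at E10.5, 43.7% at E11.5 and 62.1% at E12.5. A mitochondrial maximum of 10% gave 27.8% at E8.5, and 25% gave 39.2, 27.6, 22.5, 37.7 and 56.7% in the order of days. Without doublet removal it was 42.9% at E7.5, 27.5% at E8.5 and 52.8% at E12.5. Resolution 0.5 gave 39.3, 27.3, 22.3, 37.8 and 56.7%, and resolution 2 gave 40.6% at E7.5 and 22.3, 37.5 and 56.5% from E10.5 on. With 4000 variable genes it was 15.7, 31.5 and 45.8% from E10.5 on. Each library clustered on its own gave 39.8% at E7.5, 27.7% at E8.5, 35.1% at E11.5 and 34.8% at E12.5. The class of each cell from its own marker score gave 41.9% at E7.5 and 32.9% at E11.5. Clustering without the gene families gave 46.5% at E7.5 and 22.3, 38 and 56.9% from E10.5 on. Chosen after seeing the data, leaving out clusters 12 and 25 gave 33.4, 26.2, 16.8, 32.0 and 48.1%, and counting cluster 16 gave 22.3, 37.5 and 56.5% from E10.5 on. E10.5 had the lowest share under every setting. Whether E12.5 was above E7.5 depended on the setting, since it was not where each library was clustered on its own.

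Single classes moved more, and the cause was not tested. Parietal giant cell-like cells at E7.5, 11.4%, were 27.5% with a mitochondrial maximum of 10% or without the gene families, against 20.1 and 21.3% at E8.5. Spongiotrophoblast-like cells at E10.5, 2.52%, were 0.471% at resolution 2, where glycogen trophoblast-like cells (10.7%) outnumbered them at E11.5. Glycogen trophoblast-like cells at E7.5, 14.5%, were 1.34% with libraries apart and 4.01% by scores per cell, and at E10.5 3.03% with 200 genes and 2.48% with libraries apart. Epiblast and primitive streak-like cells at E7.5, 19.3%, were 6.37% with a mitochondrial maximum of 25%, 8.02% without doublet removal and 8.08% with 4000 variable genes. Endothelial-like cells at E10.5, 3.75%, were 0.127% with 4000 variable genes, 0.163% without the gene families and 0.212% without doublet removal. Stem/extraembryonic ectoderm-like cells at E7.5, 7.03%, were 1.25% with a mitochondrial maximum of 25%, and decidual stroma-like cells at E10.5, 2.70%, were 0.0543% at resolution 0.5.

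The log2 ratio of Prl3d1 at E12.5 over E7.5, -9.22, was -6.74 as a mean over cells, -9.69 without doublet removal, -11.59 with classes per library, -8.77 with 1 CPM added and -9.74 with cluster 16 counted. That of Prl3b1, 9.87, was 11.73 as a mean over cells, 9.43 without doublet removal, 11.06 with cells thinned to 2000 UMIs, 9.57 with classes per library, 9.37 with 1 CPM added and 9.35 with cluster 16 counted. Both kept their direction.

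Some smaller ratios reversed, and the cause was not tested. At E8.5 over E7.5, Id2 was 1.1 and Eomes 0.92 in all kept cells, Prl3d1 1.15 as a mean over cells and 0.77 with thinned cells, and Ldha 0.013 and Gapdh -0.014 as a mean over cells. H19 was -0.0042 in all kept cells. Prl3b1 at E12.5 over E11.5 was -0.27 with classes per library, and Kitl at E11.5 over E10.5 was 0.72 in all kept cells. At E12.5 over E7.5, Phlda2 was -0.74 as a mean over cells, -0.26 with thinned cells and -0.11 in all kept cells, and Sparc was -0.95 in all kept cells. Hilpda in NK-like cells at E12.5 over E11.5 was 0.27 as a mean over cells.

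The embryonic share of globin was 77.8% at E11.5 and 70.2% at E12.5 in all kept cells, and 77.8 and 70.1% without doublet removal, which differed only beyond the very narrow counting interval. The share of trophoblast-like cells with a Y-linked UMI was 7.51, 10.1, 14.9, 9.49 and 8.60% with cells thinned to 2000 UMIs, as fewer UMIs per cell must give.

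Of 1035 gene ratios, 791 stayed within their interval under TMM scaling and none reversed, and 504 did as a mean over cells, where 5 reversed. Of 971, 717 stayed without doublet removal. Of 204 ratios in trophoblast-like cells, 42 stayed with thinned cells, 67 with classes per library, 149 with 1 CPM added, 145 without abundant families in the total, 107 with cluster 16 counted and 46 in all kept cells. Of 828 list medians, 625 stayed with a minimum of 5 UMIs, and of 741, 553 with 100 UMIs. Of 100 class shares, 78 stayed with 4000 variable genes, 44 with scores per cell, 78 without the gene families, 57 with libraries apart, 26 with 1000 genes, 36 with 200 genes, 81 and 85 with mitochondrial maximums of 10 and 25%, 72 without doublet removal and 63 and 83 at resolutions 0.5 and 2. Depth limits the parietal giant cell-like, stem-like and syncytiotrophoblast-like classes on the days with fewer than 100 cells, which were not compared.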

Other observations

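Cells of cluster 16 reached no class by score, and their best list scored -0.0102. They held Alpl, the alkaline phosphatase of the placenta, Mfsd2a, a carrier of omega-3 lipids, Lpl, and the homeobox genes Rhox6 and Rhox9. Ghrh, which encodes the growth hormone-releasing hormone that the placenta also makes, was higher at E11.5 than at E10.5 and lower again at E12.5. Ctsr, a placental cathepsin, went the same way.

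Cluster 16 held 178, 449 and 574 cells at E10.5, E11.5 and E12.5, with median UMIs of 18599.5, 29081 and 31304. Ghrh was 8.31-fold (7.04 to 9.88) higher at E11.5 than at E10.5 (36.9 and 307 CPM, with 0 and 7.4 in lymphocyte-like cells), and stood at 0.199 (0.187 to 0.213) at E12.5 over E11.5. Cited1, a coregulator needed for labyrinth growth, was at 51.6 and 355 CPM at E10.5 and E11.5. Matrix genes were higher in 8 of 9 at E11.5 (median 1.85, percentile 100) and lower in 10 of 10 at E12.5 (median -0.98, percentile 0), but erythroid-like cells moved with them, so this is not read as a trait of the cluster.

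Among the tests of low Igf2, the test of the 3' end was chosen only after the result was seen. Igf2, an imprinted growth factor and among the most abundant placental transcripts in other work, was at only 5.33, 5.99, 6.19, 8.15 and 9.13 CPM in trophoblast-like cells in the order of days, so its level here is not read as biology. Gm49394 (chromosome 7, 142650769 to 142669942) lies over Igf2 (chromosome 7, 142650766 to 142666816) on the same strand, and reads that fit both genes may have been dropped. Protein-coding genes with at least 90% of their exonic bases covered in this way were under 1 CPM 2.18 times as often as others, but Igf2 is covered over 62.8% and so is not among them, and this test cannot tell. Of its last 500 bases 99.4% are covered, and genes with such 3' ends were under 10 CPM 1.53 times as often as others (95% of 343 against 62.1% of 21631), which fits a loss of 3' reads by a small margin. This decides little, since most other genes were under 10 CPM as well and the ratio had little room to rise. Covered genes that are low for other reasons would also give it. No biological explanation was tested.

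Among the tests of low Y-linked RNA in epiblast and primitive streak-like cells at E8.5, the thinning and Xist tests were chosen only after the result was seen. Ddx3y, Eif2s3y, Uty or Kdm5d was found in 5.15% (3.33 to 7.57) of 466 such cells, against 28.2% at E7.5 and 40.7% in cluster 31 at E8.5, which scored as fetal mesenchyme but is given by number because its leading genes include Tagln and Acta2 of smooth muscle. Lower depth does not account for it, since after thinning the share was 1.55% of 323 cells, with 143 left out. Maternal cells do not either, since their markers gave a summed share of 1.56% by the median marker of each class, where 83.4% was needed, which met the limit set beforehand. The highest marker of each class summed to 38%, which did not meet that limit, but a single decidual stroma marker alone gave 36.4%, and whole cells would bring all their markers. Xist was 3.80 times as high as in cluster 31 (1113 against 293 CPM), so these cells may have come mostly from female embryos, which leaves open how the pool was mixed. The class itself depends on the setting. At E8.5 it made up 0% of kept cells with each library clustered on its own and 1.30% by scores per cell.

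All tests of transcript length were chosen only after the result was seen. Protein-coding genes whose longest transcript is under 1000 bases were higher at E10.5, by their median, than on the days beside it. In lymphocyte-like cells the median log2 ratio of short minus long genes was 0.84 at E10.5 over E8.5 and -0.50 at E11.5 over E10.5, and macrophage-like cells gave 0.60 and -0.49, which fits a difference of the whole E10.5 library. A few abundant genes taking more of the counts does not account for it, since it moves all genes alike and the difference in trophoblast-like cells was 0.36. Whether handling, chemistry or sequencing may lie behind it stays open, so short genes are best not compared with E10.5. Trophoblast-like cells also had lower short genes at E12.5 than at E11.5 (-0.29, against -0.13 in lymphocyte-like cells), and NK-like cells had higher short genes at E8.5 than at E7.5 (1.08, with 89 cells at E7.5), so differences linked to length are not confined to that library.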
